A study of Aedes aegypti with 12 samples.

How the data were processed

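The series holds 12 RNA-seq libraries, from brain and fat body of wild-type (Liverpool) and AaegGr34 mutant *Aedes aegypti*, with 3 libraries per group. Per the labels, polyA RNA was fragmented, copied with random primers and made into libraries with the NEBNext Ultra II kit. Per the submitters' processing notes, FastQC, STAR, featureCounts (Subread) and DESeq2 were used, with no versions. How multi-mapped reads and strand were handled is not given in the sources used here, so reads of overlapping genes, of genes on opposite strands and of near-identical copies cannot be assigned with certainty. The genome build is not given in the sources used here. Of 19256 genes in the deposited tables, 18399 matched the reference gene table of AaegL5.0, and 18363 of 18393 with positions in both had the same start and end, so positions are given on AaegL5.0. The deposited tables place 113 genes on a chromosome that the reference table leaves unplaced; these were treated as unplaced and no position is printed for them.

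The authors deposited estimated counts per gene and library. They were not all whole: 25.39% of the values had a fraction, in 11422 genes, which is what splitting reads among genes would give, although the sources used here do not state it. The authors also deposited TPM values. The authors' deposited tables of DESeq2 results hold, per the file headers, a mean normalized count, a log2 fold change, a test score and p-values for each tissue. They were used only to count shared calls and to give the adjusted p of a few genes not called here. Counts were rounded to whole numbers. No count was recorded for 1395 genes in any library. Total counts ran from 18.5 M to 31.3 M per library. Floors and bounds cover counting error only, since the reads carry no molecular identifiers.

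Each tissue was fitted apart on its 6 libraries with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (count of 10, total of 15), robust dispersions and the two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Called" means an adjusted p under 0.05. The difference between tissues was a contrast in a fit of all 12 libraries. Overlap between tissues was tested with Fisher's exact test. The median log2 fold change over all genes was 0.00607 in brain and -0.00365 in fat body with TMM, and its sign turned with DESeq2 size factors (-0.00166 and 0.00901). CPM values use TMM-scaled library sizes, and fold changes are mutant over wild type on the log2 scale. Where a group was at 0 in all libraries, the fold was bounded with 3 counts over the group. Gene lists were tested with limma 3.58.1 camera (correlation 0.01, prior count 2), for lists with at least 5 tested genes, beside camera with an estimated correlation and fry. The 38 lists were text patterns on gene descriptions, so some members do not do what the list is named for. Only some of the called members of this kind are named below. Gene Ontology terms with 10 to 500 tested genes, as the deposited tables annotate them, were tested with one-sided Fisher's exact tests, higher and lower genes apart, against all tested genes with a term.

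The groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took, per tissue, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in a genotype, no overlap between genotypes and a description other than uncharacterized. For each list that passed camera or had at least 3 called members it took the 2 called members with the smallest adjusted p in each direction, and for the insulin, yolk, lipid and sugar lists also the most abundant member. For the difference between tissues it took the 5 genes with the smallest adjusted p in each direction. Of 96 genes so named, 27 overlap another annotated gene, 20 of them a gene on the other strand, 6 have a copy with near-equal counts in each library, and 68 have counts that are not whole numbers; all of these are uncertain to that extent. Fold changes in this set that overlap another gene include those of torso, trypsin-1, diuretic hormone class 2, aminopeptidase N and choline O-acetyltransferase.

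Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library size only, no filter beyond a total above 0, a filter of 1 CPM in 3 libraries, all 12 libraries in one fit, a replicate block, a 2-fold minimum, limma on log2(TPM + 1) and log2(TPM + 0.1), and each library left out in turn. Terms of 5 to 200 genes were tried for Gene Ontology. Alternatives added after the data were seen were the newer quasi-likelihood method of the same edgeR version, genes with whole counts only, gut and ovary marker scores as covariates in fat body, the leave-one-out for Gene Ontology terms and the alternatives for tissue identity.

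The fits were tested on simulated data with the real means, depths and spread and 200 changed genes. In brain, 14.9, 55.2 and 90.9% of genes changed by 1.5, 2 and 4 times were recovered, and 7 of 114 calls were false. In fat body, 0, 0 and 12.1% were recovered, with 0 false among 8 calls. For the difference between tissues, 0, 0 and 48.5% were recovered, with 1 false among 33 calls.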

Results

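RNA was sequenced from the brain and from the fat body of the yellow fever mosquito *Aedes aegypti*. The fat body is the insect organ that stores lipid and glycogen and secretes yolk and blood proteins. Wild-type mosquitoes of the Liverpool strain were compared with mosquitoes carrying a mutation in AaegGr34, a gustatory receptor gene, within each tissue. Each of the 4 groups had 3 libraries, which made 12 in all. The libraries are called biological replicates, and nothing more is stated about the animals, pools or days behind them. The p-values measure the spread between these libraries only. Sex, age and feeding state at dissection are not given in the sources used here. The total counts were 31.3 M, 22.6 M and 20.7 M in the wild-type brain libraries and 20 M, 21 M and 21 M in the mutant brain libraries. In fat body they were 24.3 M, 20.3 M and 20.8 M in wild type and 20.8 M, 23.8 M and 18.5 M in the mutant. Between 10772 and 12167 genes per library had at least 10 counts. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom of 20.8 to 315). The common biological coefficient of variation was 0.210 in brain and 0.406 in fat body.

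Gr34 itself (LOC5570009, AAEL000162) was read first in every library. The gene lies on chromosome 3 of AaegL5.0 at 212688192 to 212705120, on the minus strand, with 14 exons, and the files give it a second designation, gustatory receptor for sugar taste 43a. In brain the gene had 24, 22 and 7 counts in wild type and 6, 11 and 28 counts in the mutant, or 0.69 ± 0.30 and 0.72 ± 0.56 CPM (counts scaled to a common library size; SD, n = 3). The log2 fold change was 0.03 with a standard error (SE) of 0.60, and the adjusted p of edgeR's quasi-likelihood test was 0.985. Its sign turned without wild-type brain replicate 3 (-0.25) and without mutant brain replicate 3 (-0.79). In fat body Gr34 had 2, 4 and 16 counts in wild type and 2, 11 and 2 counts in the mutant, too few to enter the test. A difference in Gr34 transcript was not detectable at this depth. The position of the lesion is not given in the sources used here, so the transcript level does not check the genotype labels.

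The tissue labels were checked in the wild-type libraries with marker lists. Of 35 fat body markers tested, 23 were higher in fat body and 5 in brain, with a median log2 difference of 2.24 (fat body minus brain). Of 98 neuron and glia markers, 65 were higher in brain and 20 in fat body (median -2.72). Photoreceptor markers were higher in brain for 29 of 58 and in fat body for 12, and muscle markers were higher in brain for 20 of 51 and in fat body for 8. Ovary and germline markers were higher in fat body for 17 of 25 and in brain for 4 (median 5.30). Their transcripts varied within both genotypes, at 0.124, 0.473 and 0.673% of counts in wild-type fat body and 0.176, 0.759 and 0.268% in mutant fat body.

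In brain, mutant libraries differed from wild-type libraries in 1050 of 11848 genes tested, 545 higher and 505 lower in the mutant. Among the largest increases by the naming rule, Sur (LOC5577471), the sulfonylurea receptor subunit of ATP-sensitive potassium channels, rose from 1.39 ± 0.64 to 60.3 ± 5.5 CPM (SD, n = 3). The putative phospholipase A1 magnifin (LOC5568614) rose from 0.404 ± 0.092 to 16.97 ± 3.76 CPM. Battenin (LOC5572584), a lysosomal membrane protein, rose from 3.74 ± 0.63 to 33.6 ± 5.7 CPM. Among the largest decreases by the same rule, trfA (LOC5576294), listed as a general transcriptional corepressor, fell from 29.4 ± 4.4 to 4.01 ± 0.75 CPM. Choline O-acetyltransferase (LOC5573378), the enzyme that makes acetylcholine, was named through its gene list and fell from 45.8 ± 5.6 to 12.7 ± 2.6 CPM.

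The log2 fold changes of these genes were 5.45 (SE 0.31) for Sur, 5.37 (SE 0.26) for magnifin, 3.17 (SE 0.18) for battenin, -1.86 (SE 0.17) for choline O-acetyltransferase and -2.87 (SE 0.18) for trfA. Their adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) were 0.000319, 0.000248, 0.000319, 0.00157 and 0.000405. All 5 stayed called without any single brain library. On AaegL5.0, Sur lies on chromosome 2 at 312907331 to 313134735, magnifin on chromosome 2 at 399076057 to 399083147, and battenin on chromosome 1 at 207343708 to 207394386. Choline O-acetyltransferase lies on chromosome 1 at 204697450 to 204871254, where its annotated span overlaps that of the vesicular acetylcholine transporter gene LOC5573369 on the same strand, so counts of this gene are uncertain. trfA lies on chromosome 1 at 212918648 to 212993075.

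**Figure D1:**
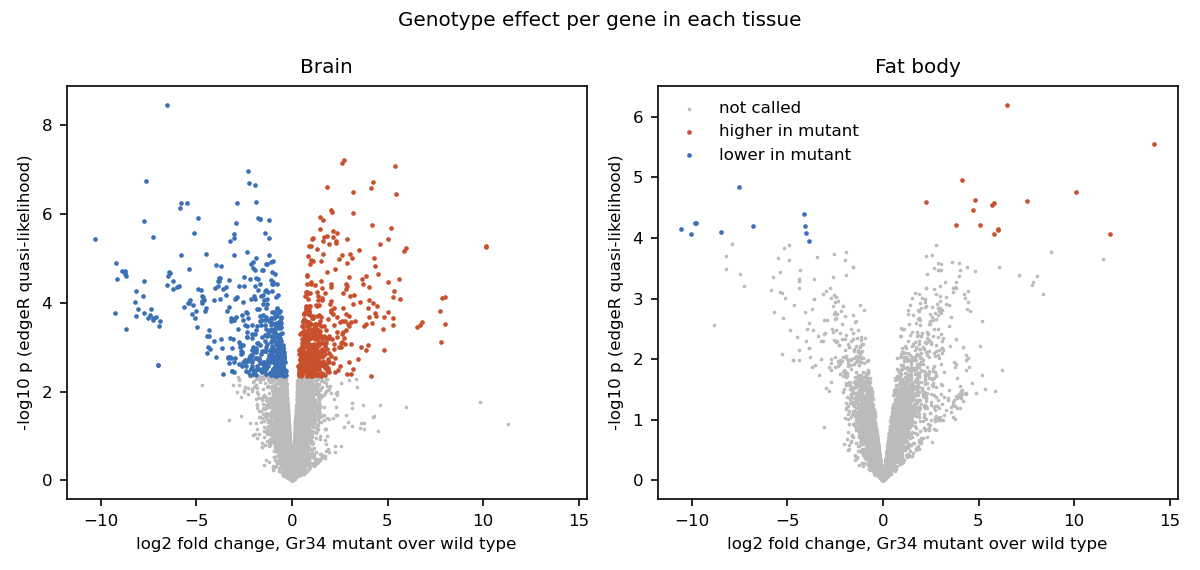
Log2 fold change (mutant minus wild type) against -log10 of the unadjusted p for every gene tested in brain and in fat body, with called genes coloured by direction. Brain has 1050 called genes and fat body 27.

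The remaining genes with the largest rises in brain by the naming rule were a gametocyte-specific factor 1 homolog (LOC5571152, log2 fold change 5.61), xanthine dehydrogenase 1 (LOC23687731, 2.96), protein AF-9 (LOC5579971, 2.88), an axonemal dynein heavy chain (LOC5564092, 2.86) and the N-acetyltransferase eco (LOC5568392, 2.82). Those with the largest falls were a helicase POLQ-like gene (LOC5575094, from 11.9 to 1.097 CPM), an enpp4-like gene (LOC110680998, log2 fold change -3.05), microcephalin (LOC5571872, -3.05), a cytochrome b5 reductase 4-like gene (LOC110675145, -2.95) and carboxypeptidase N subunit 2 (LOC5577138, from 87.6 ± 32.1 to 12.1 ± 3.8 CPM). Putative defense protein 1 (LOC5572918, -2.78), a putative nuclease HARBI1 (LOC5576377, -2.59), kelch domain-containing protein 4 (LOC5572907, -2.55) and a patj homolog (LOC110676561, -2.48) fell as well. A pair of the largest rises was mirrored by a fall of a gene of the same description. Cytochrome c oxidase subunit 7A1 (LOC5567338) rose from 8.08 to 57.7 CPM while LOC110673978 fell from 80.8 to 38.6 CPM, and mitochondrial ribosomal protein L40-like (LOC110681241) rose from 0.756 to 13.4 CPM while LOC5569568 fell from 20.8 to 10.0 CPM. The falling partners were chosen after their values were seen, and all 4 genes had counts that were not whole numbers, so their changes are uncertain. Calls were lost (edgeR adjusted p) for eco without wild-type replicate 2 (0.0618) and mutant replicate 1 (0.0563), and for the patj homolog without mutant replicate 1 (0.0652). Putative defense protein 1 lost its call without wild-type replicate 1 (0.0926) and mutant replicates 1, 2 and 3 (0.0684, 0.121 and 0.105). HARBI1 and kelch domain-containing protein 4 lost theirs without wild-type replicates 1, 2 and 3 (0.0697, 0.0788 and 0.0640; 0.102, 0.120 and 0.0775) and mutant replicate 1 (0.0960; 0.116).

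**Figure D2:**
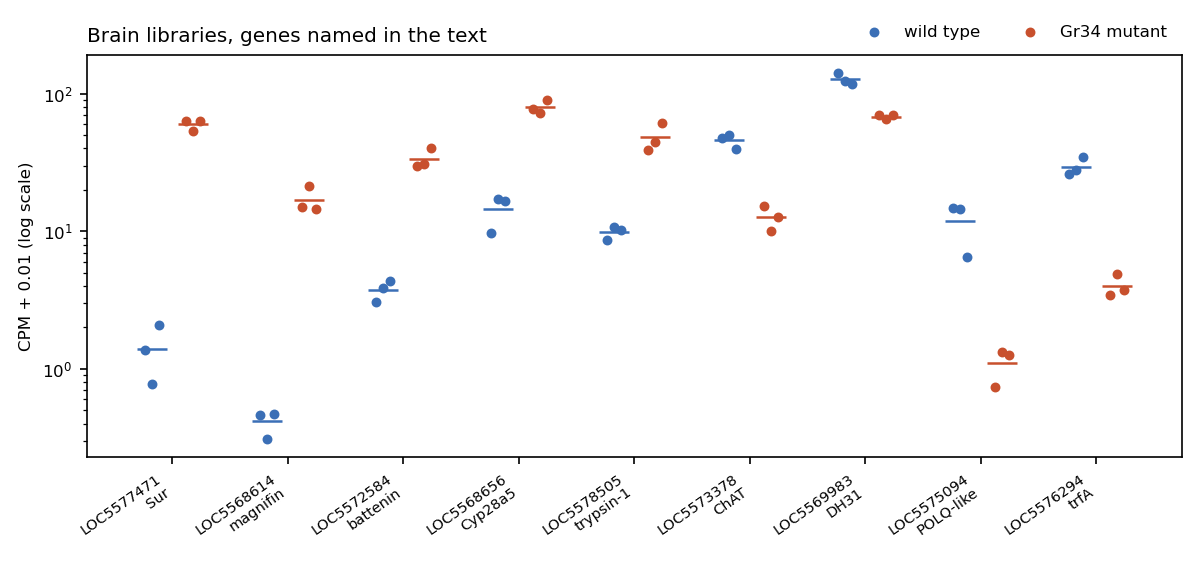
Log CPM of 9 named genes in each brain library, wild type and mutant, with points for libraries and bars for group means. The groups do not overlap for any gene shown; Sur goes from 1.39 to 60.3 CPM and choline O-acetyltransferase from 45.8 to 12.7 CPM.

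Of the 1050 brain genes, 625 changed by at least 2-fold and 407 (38.8%) were uncharacterized, against 23.5% of the genes tested. The 2 genotypes did not overlap in 3388 genes (28.6%, where chance gives 10%), including all 1050. At an unadjusted p under 0.05 there were 2705 genes. Counts that were not whole numbers occurred in 781 of the 1050 (74.4%), against 63.5% of the genes tested. The count was 463 without wild-type replicate 1, 407 without wild-type replicate 2, 405 without mutant replicate 1 and 686 without mutant replicate 2, and DESeq2 called 1730. Of 72 called brain genes fixed by the naming rule, leaving out wild-type replicates 1, 2 and 3 kept 53, 47 and 63, and leaving out mutant replicates 1, 2 and 3 kept 46, 66 and 68. All 12 libraries in one fit gave 343 called brain genes and kept 35 of the 72.

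Cytochrome P450s, heme enzymes that oxidise hormones, lipids and foreign compounds, rose as a list in mutant brain. Of 92 tested, 15 were higher and 3 lower, or 28 and 5 adjusted over the list alone, with a median log2 fold change of 0.45. Cyp28a5 (LOC5568656) rose from 14.5 ± 4.2 to 80.4 ± 9.3 CPM (log2 fold change 2.48, SE 0.23, edgeR adjusted p 0.00161) and Cyp4d2 (LOC5572942) from 0.517 to 1.94 CPM. Of the genes described as Cyp9f2, a pair fell (LOC5571141, -1.63, and LOC5564749, -0.97) and 3 rose (LOC5564754, 0.97; LOC5564756, 0.65; LOC5579929, 1.12; these 3 were named after their values were seen). The list's adjusted p was 2.85e-06 with camera at its preset correlation and 0.0357 with fry, which tests whether the list moves one way on balance; with an estimated correlation the p was 0.0172 and the adjusted p 0.618. The 100 genes most enriched in wild-type fat body, without P450s, had a median log2 fold change of 1.03 in brain, with 31 called higher and 1 lower. Their enrichment was measured against the same wild-type brain libraries, so genes low there by chance were favoured and the value is biased upward. The same bias affects every set below that was picked as higher in wild-type fat body than in wild-type brain. Of the 15 P450s called higher, 4 were among the 25 at least 2-fold higher in wild-type fat body than in wild-type brain (median 0.453), and 11 were among the other 67 (median 0.445). LOC5564749 lost its call without wild-type replicate 2 (adjusted p 0.0634) and mutant replicate 1 (0.0688), and LOC5571141 without wild-type replicates 1, 2 and 3 (0.0895, 0.0998 and 0.0565) and mutant replicate 1 (0.0983).

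Fat body markers and sugar transporters also passed in the upward direction. Of 29 fat body markers, 1 rose, hexamerin-1.1 (LOC5579047, 3.05 to 8.23 CPM), and 1 fell, 4-hydroxyphenylpyruvate dioxygenase (LOC5564745, 13.1 to 7.05 CPM), or 4 and 1 adjusted over the list alone (median 0.36; camera adjusted p 0.00429; p = 0.0602 with an estimated correlation). Without mutant brain replicate 1 the adjusted p of hexamerin-1.1 and of LOC5564745 was 0.0643, and without wild-type brain replicate 2 that of LOC5564745 was 0.0719. Fat body markers held 0.101, 0.131 and 0.134% of counts in wild-type brain and 0.158, 0.153 and 0.158% in mutant brain. Of 45 genes in the sugar transporter list, 5 rose and 0 fell, or 8 and 2 adjusted over the list alone (median 0.23; camera adjusted p 0.00394; p = 0.0633 with an estimated correlation). The clearest of the 5 was solute carrier family 23 member 2 (LOC23687387, 14.2 ± 1.2 to 35.3 ± 3.0 CPM), from a family known for ascorbate rather than sugar transport. Tret1 LOC5573437, a trehalose transporter, rose from 26.4 ± 3.1 to 44.4 ± 8.6 CPM; its edgeR adjusted p was 0.0314 with all libraries and 0.105, 0.0985 and 0.0570 without wild-type replicates 1, 2 and 3, and 0.0625 and 0.0543 without mutant replicates 1 and 2. The most abundant member, Tret1 LOC5573431, was at 208 ± 16 and 225 ± 24 CPM and was not called.

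Digestive proteases and other gut markers had 6 members higher and 1 lower of 50, and as many adjusted over the list alone (median 0.40; camera adjusted p 0.0218; p = 0.242 with an estimated correlation). Trypsin-1 (LOC5578505), a digestive serine protease, rose from 9.83 ± 1.08 to 48.2 ± 11.5 CPM and aminopeptidase N (LOC5576798) from 6.91 ± 1.18 to 26.1 ± 3.2 CPM, while zinc carboxypeptidase A 1 (LOC5573859) fell from 4.55 to 0.781 CPM. Without mutant brain replicate 2 the list's adjusted p was 0.178. Gut markers held 0.208, 0.239 and 0.260% of counts in wild-type brain and 0.299, 0.371 and 0.172% in mutant brain. Cytosolic ribosomal proteins had 3 members higher and 1 lower of 92, and as many adjusted over the list alone (median 0.22; camera adjusted p 8.55e-05; p = 0.533 with an estimated correlation). S17 (LOC110680939) rose from 362 ± 12 to 623 ± 32 CPM; the member that fell, 50S ribosomal protein L1 (LOC5565138), carries the name of a bacterial-type ribosomal protein. Of the 92, 91 were at least 2-fold higher in wild-type fat body than in wild-type brain, including all 3 called higher; ribosomal proteins held 28.2 ± 4.8% of counts in wild-type fat body and 7.86 ± 0.62% in wild-type brain, and the 100 genes most enriched in fat body had a median log2 fold change of 1.03 in mutant brain. Without mutant brain replicate 3, which had 10.9% of its counts in ribosomal proteins against 7.26 to 9.37% in the other brain libraries, the list's adjusted p was 0.215.

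Neuropeptides with their receptors, and neurotransmitter genes, fell as lists in mutant brain. Of 35 neuropeptide genes, 0 rose and 5 fell, or 6 fell adjusted over the list alone (median -0.24; camera adjusted p 0.00284; p = 0.164 with an estimated correlation). Diuretic hormone class 2 (LOC5569983), a calcitonin-like peptide of fluid secretion, fell from 127 ± 13 to 68.3 ± 2.5 CPM, and neuropeptide FF receptor 2 (LOC5570372) fell from 1.05 to 0.0474 CPM; the adjusted p of the receptor was 0.0577 without wild-type replicate 2 and 0.0704 without mutant replicate 1. Of 99 genes in the neurotransmitter and synaptic release list, which does not hold the called higher release gene SNAP-25 (LOC5565055, 0.78, named after its value was seen), 0 rose and 4 fell, and as many adjusted over the list alone (median -0.12; camera adjusted p 0.00586; p = 0.361 with an estimated correlation). These included choline O-acetyltransferase and the kainate 2 glutamate receptor (LOC5574991, 40.2 ± 1.3 to 29.3 ± 1.0 CPM), whose edgeR adjusted p was 0.0863 and 0.0753 without wild-type replicates 1 and 2 and 0.0814 without mutant replicate 1. Without mutant brain replicate 2 the neurotransmitter list's adjusted p was 0.293. Neuron and glia markers (92 tested) had a median of -0.12 as well, but did not pass (camera adjusted p 0.121). In both lists the members at least 2-fold higher in wild-type fat body had positive medians (0.279 for 7 and 0.28 for 15). The other 92 and 77 members had medians of -0.13 and -0.183. A fall particular to neurotransmitter genes was therefore not shown. Photoreceptor transcripts held 25.9 ± 2.5% of counts in wild-type brain and 21.9 ± 0.9% in mutant brain (n = 3 each). The genotypes did not overlap in this share (lowest wild-type library 23.08%, highest mutant library 22.84%). Mitochondrial 16S ribosomal RNA, a measure that can vary with RNA and library quality, held 0.533, 0.489 and 0.579% of counts in wild-type brain and 0.696, 0.792 and 1.02% in mutant brain, with no overlap between the genotypes.

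Several lists held at least 3 called members without passing as lists. Mitochondrial ribosomal proteins had 3 higher and 7 lower of 78 (camera adjusted p 0.349), among them L37 (LOC5576132, log2 fold change 0.91) and the L43 pair LOC5580284 and LOC110681506 (-1.66 each), which had near-equal counts in each library. Oxidative phosphorylation genes had 3 higher and 6 lower of 79 (0.499), including cytochrome c oxidase subunit 5A (LOC5565701, 234 ± 28 to 448 ± 52 CPM). Immune genes had 6 higher and 3 lower of 70 (0.0503), with peptidoglycan-recognition protein LC (LOC5576901) at 0.71 and lysozyme c-1 (LOC23687552) at -0.81. Malpighian tubule markers had 7 higher and 1 lower of 52 (0.746); V-ATPase subunit d 1 (LOC5574244) rose from 26.6 ± 2.8 to 81.0 ± 10.7 CPM. Cuticle genes had 7 higher and 4 lower of 64 (0.804), glutathione transferases, esterases and UDP-glycosyltransferases 6 and 4 of 76 (0.746), and photoreceptor markers 4 and 4 of 54 (0.176). The called photoreceptor members included arrestin domain-containing protein 3 (LOC5570223, -3.80) and retinol dehydrogenase 12 (LOC5565044, -0.99), whose families are not restricted to the eye. Amino acid transporters had 4 higher and 1 lower of 40 (0.562), olfactory genes 3 and 1 of 50 (0.217), with Or10 at 2.05 and Or16 at -5.66, and testis markers 1 and 2 of 30 (0.876). Lipid storage genes had 3 higher and 0 lower of 19 (0.145), led by a lipase 3-like gene (LOC110674343, 0.79) and Lsd2 (LOC5568403, 0.72). All 6 immune genes and all 3 lipid storage genes called higher were at least 2-fold higher in wild-type fat body than in wild-type brain, as were 4 of the 6 glutathione transferases, esterases and UDP-glycosyltransferases called higher. The 40 immune and 10 lipid storage members enriched in fat body had medians of 0.707 and 0.755, and the other 30 and 9 had medians of 0.174 and 0.0746 with 0 called higher. Fat body markers passed upward in mutant brain with camera at its preset correlation only (p = 0.0602 with an estimated correlation). The other lists had adjusted p-values of up to 0.917. Fatty acid synthase (LOC5568814) was at 409 ± 75 and 592 ± 102 CPM, apolipophorins (LOC5572681) at 617 ± 125 and 827 ± 113 CPM, and trehalase (LOC5572224) at 325 ± 48 and 443 ± 37 CPM in wild type and mutant, and none of these was called by edgeR. In the authors' deposited DESeq2 results for brain, fatty acid synthase and trehalase were higher in the mutant (adjusted p 0.0316 and 0.0232). Apolipophorins did not pass there (0.138). Calls were lost for L37 without wild-type replicates 1 and 3 (edgeR adjusted p 0.0775 and 0.0574), for peptidoglycan-recognition protein LC without wild-type replicates 1 and 2 (0.0528 and 0.0588), for lysozyme c-1 without wild-type replicate 2 and mutant replicate 1 (0.0798 and 0.0832), and for Lsd2 without wild-type replicates 1 and 2 and mutant replicate 1 (0.0755, 0.0870 and 0.0686).

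Median, mean and test differed in sign in brain for yolk precursors, ecdysone genes, oxidative phosphorylation, the proteasome, endoplasmic reticulum folding, cuticle, ovary and Malpighian tubule markers, none of which passed. All 7 list calls in brain were lost at an adjusted p with estimated correlations, and 6 to 19 lists passed when the same 6 libraries were grouped in the other 9 ways. Scaling by library size alone kept the direction of all 7.

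Gene Ontology terms were tested with one-sided Fisher's exact tests across genes, which are not replicates. Among the genes higher in mutant brain, 13 terms were enriched, including iron ion binding (20 of 126 tested genes, adjusted p 3.83e-05), proteolysis (36 of 367, 7.09e-05), heme binding (18 of 122, 0.000174), monooxygenase activity (16 of 118, 0.00126), serine-type endopeptidase activity (21 of 190, 0.00128) and extracellular space (9 of 51, 0.00813). Among the genes lower in mutant brain, 1 term was enriched, nuclease activity (9 of 47, 0.00271). The total of 14 terms was 9 without wild-type replicate 1, 0 without wild-type replicate 2, and 2 without either mutant replicate 1 or mutant replicate 2.

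**Figure D3:**
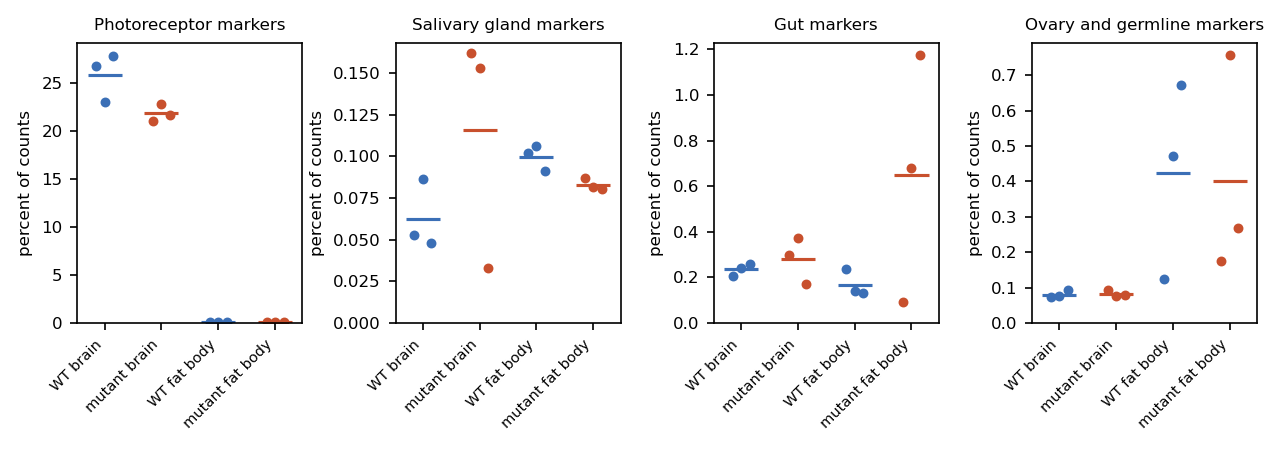
Percent of counts in photoreceptor, salivary gland, gut and ovary marker genes in each of the 12 libraries, on the y axis, by group. Photoreceptor transcripts hold 21.1 to 27.9% in brain, and gut transcripts reach 0.678 and 1.18% in mutant fat body replicates 2 and 3.

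In fat body, mutant and wild-type libraries differed in 27 of 11558 genes, 16 higher and 11 lower in the mutant. The receptor tyrosine kinase torso (LOC5574477), which receives prothoracicotropic hormone in insects, rose from 31.9 ± 14.4 to 897 ± 201 CPM (SD, n = 3). VPS18 (LOC5564402), a subunit of the complexes that tether vesicles to lysosomes, rose from 21.8 ± 2.2 to 103 ± 16 CPM. A zinc finger BED domain gene (LOC110676965) was at 0 in all 3 wild-type libraries and at 105 ± 32 CPM in the mutant, at least 2350-fold higher (floor of 3 counts over the group). Microfibril-associated glycoprotein 4 (LOC5577410) fell from 12.7 ± 7.6 to 0.0722 ± 0.0507 CPM. The zinc finger BED gene lost its call (edgeR adjusted p) without wild-type replicate 2 (0.0881) and mutant replicates 1 and 3 (0.0598 and 0.103). Torso, VPS18 and microfibril-associated glycoprotein 4 lost theirs without wild-type replicate 2 (0.251, 0.251 and 0.242) and mutant replicates 1, 2 and 3 (0.0727, 0.0538 and 0.103 for each), and torso and VPS18 also without wild-type replicate 3 (0.173).

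The log2 fold changes were 4.81 (SE 0.51, edgeR adjusted p 0.0333) for torso, 2.25 (SE 0.25, 0.0333) for VPS18 and -7.50 (SE 0.74, 0.0333) for microfibril-associated glycoprotein 4. The other named genes were Cyp4c3 (LOC5569919, 6.50, adjusted p 0.00733), an erythroid transcription factor (LOC5573046, 5.09, 0.0390), serine protease 53 (LOC5572144, 4.70, 0.0361), a digestive organ expansion factor homolog (LOC110681240, 4.12, 0.0333), mitochondrial ribosomal protein L40-like (LOC110681241, 3.83, 0.0390) and a putative nuclease HARBI1 (LOC110678556, -8.45, 0.0390). HARBI1 had 539 counts in wild-type and 1 in mutant fat body in total, so the size of its fall is uncertain. On AaegL5.0 torso lies on chromosome 2 at 214566733 to 214765147, where it overlaps LOC5567477 on the same strand and LOC5567497 on the other, so its counts are uncertain. VPS18 lies on chromosome 1 at 104599428 to 104607788 and had whole counts in every library. The zinc finger BED gene overlaps LOC110676967 on the other strand. Cyp4c3 lost its call without wild-type replicate 2 (0.0881) and mutant replicates 1 and 3 (0.0598 and 0.0728). The other 5 named genes were called in none of the fits without wild-type replicates 2 and 3 or mutant replicates 1, 2 and 3 (adjusted p 0.0538 to 0.251), and L40-like was also not called without wild-type replicate 1 (0.0654).

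**Figure D4:**
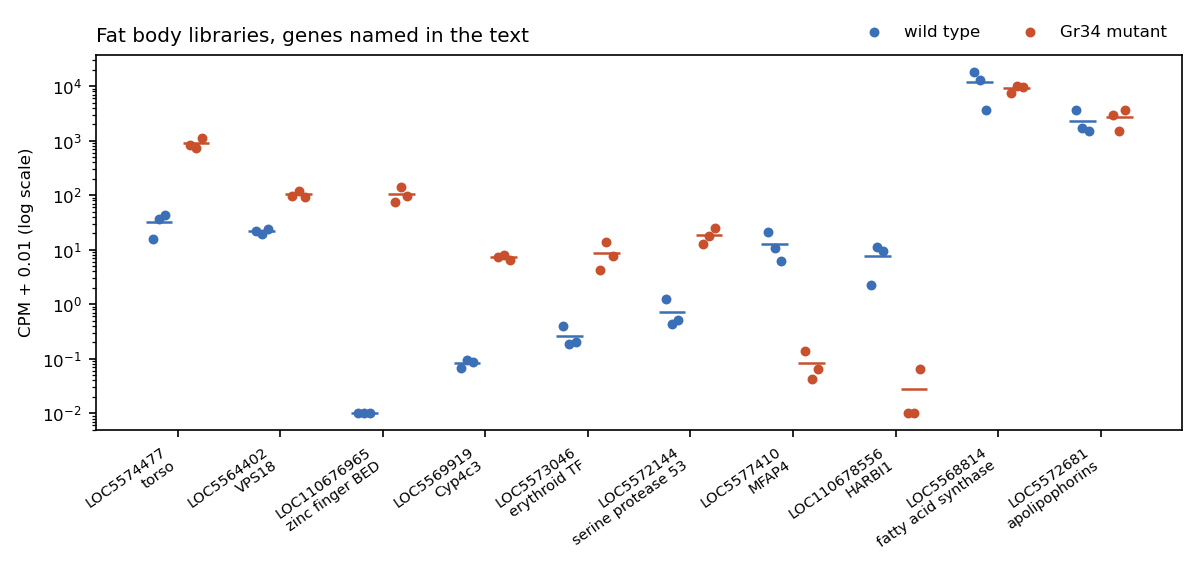
CPM + 0.01 on a log scale for 10 named genes in each fat body library, with points for libraries and bars for group means. Torso goes from 31.9 to 897 CPM and VPS18 from 21.8 to 103 CPM, while fatty acid synthase and apolipophorins overlap between the genotypes.

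All 27 genes changed by at least 2-fold, and 24 of them (88.9%) had counts that were not whole numbers. At an unadjusted p under 0.05 there were 907 genes, DESeq2 called 381, and the genotypes did not overlap in 1276 genes (11%, where chance gives 10%). The count was 37 without wild-type replicate 1 but 0 without wild-type replicate 2, 3 without wild-type replicate 3, and 0, 4 and 0 without mutant replicates 1, 2 and 3. Scaling by library size alone left 1 gene called.

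The genes of reserve metabolism named by rule were not called in fat body. This does not show that they were unchanged. In simulated fat body data 0% of genes changed by 2 times and 12.1% of those changed by 4 times were recovered. Fatty acid synthase (LOC5568814) was at 11745 ± 7434 CPM in wild type and 9076 ± 1395 CPM in the mutant, apolipophorins (LOC5572681) at 2264 ± 1162 and 2680 ± 1112 CPM, and Lsd2 (LOC5568403) at 1095 ± 329 and 909 ± 137 CPM. Trehalose-phosphate synthase (LOC5568007) was at 882 ± 451 and 811 ± 75 CPM, Tret1 LOC5565788 at 429 ± 210 and 678 ± 304 CPM, and the 4E-binding protein gene LOC5572651 at 428 ± 152 and 485 ± 147 CPM. None of the lists for insulin signalling, yolk precursors, lipid synthesis, lipid storage, trehalose and glycogen, or sugar transport had a called member or passed camera (adjusted p 0.728, 0.914, 0.0814, 0.787, 0.787 and 0.616).

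Of the lists, 4 passed camera in fat body. Mitochondrial ribosomal proteins fell as a list of 78 (median -0.19; adjusted p 0.000752; p = 0.484 with an estimated correlation), although the 1 called member, L40-like (LOC110681241), rose, and 1 was higher and 2 lower adjusted over the list alone. Digestive proteases and gut markers rose (66 tested; median 0.87; adjusted p 0.00389; p = 0.342 with an estimated correlation) with 0 called members; gut transcripts held 0.235, 0.139 and 0.131% of counts in wild type and 0.0923, 0.678 and 1.18% in the mutant. Histones (28 tested; median 0.30; adjusted p 0.0114; p = 0.311 with an estimated correlation) and endoplasmic reticulum folding and secretion (78 tested; median 0.20; adjusted p 0.0247; p = 0.575 with an estimated correlation) rose with 0 called members, over all genes or adjusted over the list alone. The P450 list had 1 member higher of 96, Cyp4c3, or 5 higher and 1 lower adjusted over the list alone (0.620). The mitochondrial ribosomal list had an adjusted p of 0.561 without wild-type replicate 1 and 0.244 without mutant replicate 2, and the gut list 0.0732 and 0.302 without mutant replicates 2 and 3. The histone list turned downward without wild-type replicate 1 (0.872) and had 0.0860 without mutant replicate 2, and the endoplasmic reticulum list had 0.586, 0.139, 0.703 and 0.126 without wild-type replicates 2 and 3 and mutant replicates 1 and 3. fry passed 0 lists, camera passed 6 to 24 in the other groupings of the 6 libraries, and 0 Gene Ontology terms were enriched by Fisher's exact test on the edgeR calls, against 10 on DESeq2 calls. The median and the test differed in sign for lipid storage, glycolysis, immune, cuticle, ovary and testis lists, none of which passed.

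Among 10642 genes tested in both tissues, 17 were called in both, 10 higher and 7 lower in the mutant, each with the same direction in brain and fat body. Independent lists of 861 brain and 20 fat body genes would share 1.62, or 0.504 in the upward and 0.315 in the downward direction (Fisher's exact p 2.13e-16 across genes, which are not replicates). Torso rose in both tissues (log2 fold change 1.75 in brain and 4.81 in fat body), as did serine protease 53 (1.51 and 4.70) and a digestive organ expansion factor homolog (LOC110681240, 5.17 and 4.12). Microfibril-associated glycoprotein 4 fell in both (-4.68 and -7.50), with a piggyBac-derived gene (LOC110679851, -3.88 and -4.01) and HARBI1 LOC110678556, which was at 0 in all 3 mutant brain libraries (at least 69.3-fold lower, floor of 3 counts over the group) and at -8.45 in fat body. That fat body value rests on 1 mutant count in total, below the floor of 3. The others were L40-like and 10 uncharacterized genes. Among the 17 there were 3 pairs with near-equal counts in each library (LOC110676361 with LOC110676961, LOC110681396 with LOC110678865, LOC110675315 with LOC110677934), so 14 remain with each pair counted once, and the Fisher p counts such copies as separate genes. Of the 861 brain calls, 628 (72.9%) had the same sign in fat body, against 55.2% of the other genes. DESeq2 called 161 in both, 71 higher, 79 lower and 11 in opposite directions; without wild-type fat body replicate 1 there were 17, of which 1 went opposite ways. The count was 0, 1, 0, 2 and 0 without wild-type fat body replicates 2 and 3 and mutant fat body replicates 1, 2 and 3.

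**Figure D5:**
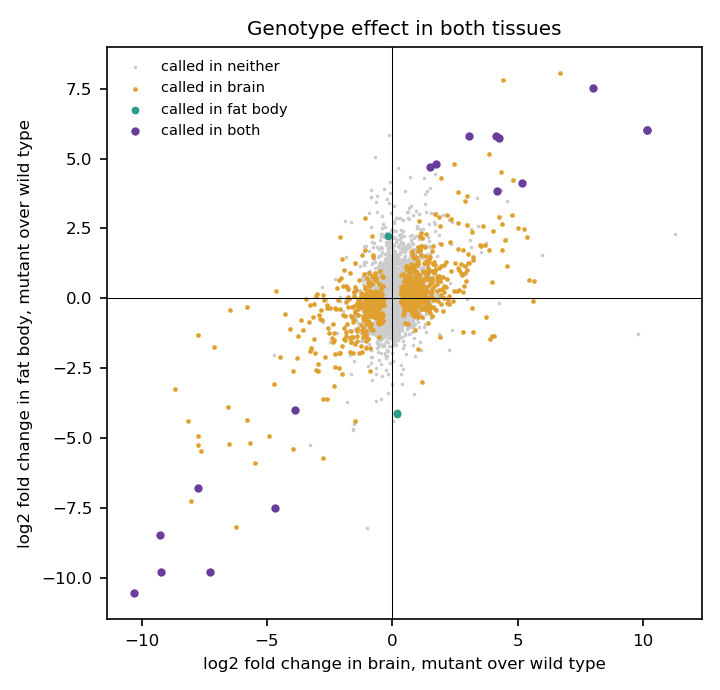
Log2 fold change (mutant minus wild type) in brain on the x axis and in fat body on the y axis for genes tested in both, with the 17 genes called in both marked. All 17 lie on the side where both tissues have the same sign.

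A test of the difference itself, the genotype effect in fat body minus that in brain, called 60 of 12859 genes, 41 above 0 and 19 below. That balance was not stable: 61 above and 18 below without mutant fat body replicate 1, 40 and 43 without wild-type fat body replicate 1, and 10 and 10 with a replicate block. Sur rose in brain (5.45) and was at 0.66 in fat body without a call there, a difference of -4.74 (SE 0.51, edgeR adjusted p 0.00642). Battenin differed by -3.48 (SE 0.38, 0.00642), with 3.17 in brain and -0.34 in fat body. VPS18 differed by 2.46 (SE 0.26, 0.00642), with -0.17 in brain and 2.25 in fat body. The monocarboxylate transporter 8 gene (LOC5575506), a thyroid hormone transporter in vertebrates, fell in brain (-0.81), was at 2.23 in fat body without a call, and differed by 3.07 (SE 0.37, 0.00863). At an unadjusted p under 0.05 there were 1161 genes, and DESeq2 called 249. The count was 14, 36 and 13 without wild-type fat body replicate 2 and mutant fat body replicates 2 and 3. It was 14, 15 and 16 without wild-type brain replicates 1, 2 and 3 and 10, 18 and 15 without mutant brain replicates 1, 2 and 3.

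In the authors' deposited table for brain, 1728 genes had an adjusted p under 0.05, 911 higher and 817 lower in the mutant, and in the authors' deposited table for fat body there were 384, 218 higher and 166 lower. Of the genes called here, 1036 of the 1050 in brain and all 27 in fat body were also called in the authors' deposited table, with the same sign. DESeq2 run here called 1730 and 381 genes, of which 1710 and 373 were called in the authors' deposited table.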

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

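The gut and ovary marker covariates were chosen after the data had been seen, the gut one first and the ovary one after the gut result, a split of the fat body libraries and the ovary shares; the predictions of the other tests in this part were written before their results were seen.

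A difference between groups put 10 genes here: their genotype effect in fat body minus that in brain passed the test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg). The difference was 2.46 for VPS18 (LOC5564402, adjusted p 0.00642), 3.07 for monocarboxylate transporter 8 (LOC5575506, 0.00863), 2.97 for sodium/potassium/calcium exchanger 4 (LOC5565499, 0.0228), 7.35 for a glucose dehydrogenase (LOC5563975, 0.0247) and 3.26 for serine protease 53 (LOC5572144, 0.0254). It was -4.74 for Sur (LOC5577471, 0.00642), -3.48 for battenin (LOC5572584, 0.00642), -1.77 for zinc finger protein 99 (LOC5571247, 0.00863), -4.34 for matrix metalloproteinase-2 (LOC5580306, 0.0134) and -3.14 for magnifin (LOC5568614, 0.0228). The glucose dehydrogenase had too few counts to be tested in brain alone, and was at 2.57 in fat body without a call (0.125). Without single libraries the exchanger lost its call in 7 of 12 fits (adjusted p up to 0.0874), the glucose dehydrogenase in 7 (0.107), serine protease 53 in 8 (0.103), magnifin in 8 (0.0873) and matrix metalloproteinase-2 in 2 (0.0549); the other 5 kept theirs. Calls were lost without mutant fat body replicate 3 for all 5 of these genes, without wild-type fat body replicate 2 for all but the exchanger and matrix metalloproteinase-2, and otherwise without brain libraries. The exchanger fell in brain (-1.93) and was at 1.00 in fat body, and serine protease 53 rose in both tissues (1.51 and 4.70).

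Among 60 groupings of the libraries, the real one and others drawn at random, 4 gave at least as many genes as the 60 of the genotypes, with a highest of 765, so chance was not excluded for that count. The others that did (765, 204 and 765 genes) all set wild-type fat body replicate 1 with mutant fat body replicates 1 and 3. A further draw with that fat body grouping gave 1 gene.

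Fewer genes were called in fat body (27) than in brain (1050), at a similar depth (ratio of median totals 0.989). Brain fold changes given to 861 genes in simulated counts with the fat body's spread led to a median of 170 calls (138 to 183), which is consistent with the larger spread as part of the cause. For gut RNA in some libraries, the prediction of more calls was not met: with the gut marker score as a covariate 1 gene was called. The high gut shares, 0.678 and 1.18% of counts, were both in mutant libraries, and 16.1% of that score's variance is shared with genotype. The covariate can therefore remove a genotype effect, and the result does not decide whether gut RNA adds to the spread. Ovary RNA, or another difference in composition that follows it, may account for part of the spread. With the ovary marker score as a covariate, which shares 0.802% of its variance with genotype, 283 genes were called, including all 27. Ribosomal proteins held 28.39 to 37.04% of counts in wild-type replicate 1 and mutant replicates 1 and 3, which had the lowest ovary shares. They held 22.15 to 26.44% in the other fat body libraries, so the covariate cannot tell ovary RNA from such a difference. A smaller effect of the genotype in fat body was not separated from these.

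For fat body genes, 2 of the 10 splits of the 6 libraries, the real one included, gave as many as 27. The highest other, 1451, set wild-type replicate 1 with mutant replicates 1 and 3. These are the 3 libraries with the lowest ovary shares and also the highest ribosomal protein shares. The real grouping gave 4 lists and 0 Gene Ontology terms, all 10 splits gave as many of each, and the highest others were 24 and 59. With 10 splits there are too few for a share under 0.05.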

How the results depend on the processing

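The newer quasi-likelihood method, whole-number counts, the marker covariates, the leave-one-out for Gene Ontology terms and the alternatives for tissue identity were chosen after seeing the data; the other alternatives were planned. Genes changed in brain numbered 1730 with DESeq2, 343 with all 12 libraries in one fit, 625 with a 2-fold minimum, 266 with whole-number counts only (fewer genes tested) and 405 to 979 without single libraries. In fat body they numbered 381 with DESeq2, 1 with library size only, 55 with no filter, 362 with all 12 libraries in one fit, 50 on log2(TPM + 0.1), 60 with the newer method, 3 with whole-number counts, 1 with the gut score, 283 with the ovary score and 0 to 37 without single libraries. Genes that differed between tissues numbered 249 with DESeq2 and 10 to 83 without single libraries; genes changed in both numbered 161 and 0 to 17. Lists in brain numbered 0 with an estimated correlation, 1 with fry and 5 to 11 without single libraries; in fat body 0, 0 and 2 to 13. Gene Ontology terms in brain numbered 23 with DESeq2 calls, 7 with terms of 5 to 200 genes and 0 to 16 without single libraries; in fat body 10 with DESeq2 calls.

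Gr34 in brain turned to -0.15 with limma-voom, -0.0200 on log2(TPM + 1) and -0.0814 on log2(TPM + 0.1), and ran from -0.79 to 0.41 without single libraries. Without single libraries LOC5580214 in brain ran from -0.10 to 2.19; in fat body LOC5572651 ran from -0.00902 to 0.53, LOC5572681 from -0.00139 to 0.77, LOC5568814 from -0.80 to 0.10 and LOC5568007 from -0.41 to 0.37, and was 0.0674 with the ovary score. No called gene reversed. Over all alternatives, values of single named genes kept direction and side of the threshold in 1258 cases in brain, 249 in fat body and 132 for the difference between tissues; 167, 73 and 37 fell short of the threshold, and 2 in brain newly passed it. Except where fewer genes or libraries were tested, the cause was not tested.

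Whether the replicate numbers pair the samples is not stated. With group means removed, same-numbered libraries correlated at -0.00225, 0.135 and 0.241 in brain and 0.202, 0.358 and -0.264 in fat body. With 3 libraries per group, these values do not settle whether a batch was shared. A replicate block gave 767 genes in brain, 54 genes in fat body, 20 that differed between tissues, 27 in both, 7 Gene Ontology terms in brain and 2 in fat body, and -0.11 for Gr34 in brain; it kept 5 of the 10 named differences between tissues.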

Other observations

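The genes of the next paragraph were chosen after their values were seen, and the tests on copies, on the segment around Gr34, on the stock's background, on neighbouring genes and on fat body RNA as the whole cause were chosen after seeing the result they bear on.

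The fixed lists of sugar metabolism did not pass in brain: glycolysis had 1 member higher and 1 lower of 20 (camera adjusted p 0.498), and trehalose, glycogen and fructose metabolism 1 higher and 0 lower of 23 (0.0503). Among these members, phosphoglycerate mutase 2 (LOC5567423) fell from 322 ± 22 to 139 ± 4 CPM (SD, n = 3; edgeR adjusted p 0.000571), and UTP-glucose-1-phosphate uridylyltransferase (LOC5566725), which makes UDP-glucose, rose from 41.1 ± 1.1 to 81.0 ± 4.7 CPM (0.00108). Of the Malpighian tubule markers, 4 were xanthine dehydrogenases, enzymes of urate formation, and all 4 rose: LOC23687731 from 0.969 to 7.72 CPM, LOC5573280 from 0.252 to 1.72, LOC5573274 from 0.696 to 3.13 and LOC5573295 from 9.28 to 21.8. The Malpighian tubule list itself did not pass (median -0.03, camera adjusted p 0.746), and these 4 genes were not tested as a set. The synaptic vesicle fusion protein SNAP-25 (LOC5565055) rose from 552 ± 11 to 945 ± 80 CPM (0.00400); the text patterns put it among the neuron and glia markers, so it is not in the neurotransmitter list. Opsin-3 (LOC5576882) rose from 1324 ± 29 to 1751 ± 95 CPM (0.0351).

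Some genes were at or near 0 in one genotype, with at most 3 counts in total there and at least 10 counts in every library of the other: 83 in brain and 40 in fat body, of which 16 were shared, all in the same state (13 with each of 3 pairs of near-equal counts counted once). Reads moved between near-identical copies could not be told apart from chance partners: 66 of the 79 brain genes that could be examined (83.5%) had a called gene that gained what they lost in both tissues, but 84.8% had one that moved the same way by as much, a comparison added after the first value was seen. A chromosome segment within 20 Mb of Gr34, carried along with the mutation, was excluded as the main cause, since 3.74% lay there, against 3.26% of the genes tested. A longer segment was not tested. Of the 107 genes in either tissue, 35 lay on chromosome 3 with Gr34, and 27 and 36 lay on chromosomes 1 and 2, where such a segment cannot reach. Brain calls lay next to each other more often than in random draws. Among 967 placed calls there were 110 neighbouring pairs, 76 of them in the same direction, against a mean of 66.9 and a highest of 95 in 1000 draws. Pairs with the same description were left out, but uncharacterized genes were exempt, so copies among these can remain. The draws took no account of expression level or of neighbours expressed together, so the excess does not point to a cause. No expected number of pairs in the same direction was computed. The condition of more than 1 kb between neighbours was added after a first run, and unplaced genes were then left out. Genetic background of the mutant stock may be involved, as 25 of the 27 of these brain genes that were tested in fat body (92.6%; the rest of the 83 were not tested there) had the same sign, but it is confounded with the genotype here and the test cannot tell it from an effect of Gr34.

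The rise of cytochrome P450s in mutant brain was weighed against carried-over tissue. For fat body RNA in the mutant brain libraries, the prediction was met. The 100 genes most enriched in wild-type fat body had a median log2 fold change of 1.03 in brain, above the 0.449 of the P450 list. These genes were picked with the same wild-type brain libraries, which biases their fold change upward, so the test cannot decide this. A median of 0.52 was found for 20 abundant genes, also picked as higher in wild-type fat body than in wild-type brain. As the whole cause, fat body RNA of the wild-type profile did not account for 13 of the 15 called P450s. All 15 gained at least 2 times what it would bring. The 13 gained 21.8 to 505% of their wild-type fat body level, against at most 6.40% for 20 abundant fat body genes (a comparison added after the result was seen). The 15 were picked for their rise in these same libraries, and the mutant fat body profile was not used. Cyp4d1 (LOC5569663, 5.73%), Cyp4d2 (LOC5572942, 6.15%) and fat body of another composition, such as that of the mutant or of the head, stay open. The rise does not rest on the mutant library with low salivary gland transcripts, replicate 3 (0.0329% of counts; the list's adjusted p without it was 4.34e-06), but salivary gland tissue in mutant replicates 1 and 2 (0.162 and 0.153%, against 0.0528, 0.0864 and 0.0478% in wild type) was not tested and stays open. An effect of the genotype on P450 expression in brain was not tested apart from these.

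In the other splits of the 6 brain libraries, the highest count of genes was 34 against 1050, and only the real one, 1 of 10, gave as many. For brain lists 9 of 10 splits gave as many as 7, with a highest other of 19, and for Gene Ontology terms 1 of 10 gave as many as 14, with a highest other of 0. With 10 splits there are too few for a share under 0.05. For genes called in both tissues, 2 of 100 pairs of splits gave as many as 17, with a highest other of 116, a share of 0.02. The 116 can only come from the real brain split, since the highest other brain split called 34 genes. In each tissue most splits called 0 genes, so few pairs could share any gene. The share was therefore bound to be small, and it does not decide whether the overlap was due to chance.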
